A study of Mus musculus with 45 samples.

How the data were processed

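RNA was measured by bulk sequencing of poly(A)-selected libraries from mouse placenta and embryonic brain. The placentas were WT, from 2 sexes at 3 stages (E9.5, E12.5 and E17.5), with 4 libraries in each of the 6 groups. The brains were E12.5 and came from 4 genotypes: 5 WT, 6 labelled Sert KO, 5 labelled Tph1 KO and 5 labelled Oct3 KO libraries. The labels give the sex of the placentas but not that of the brains. Their numbers were read as embryo numbers, and nothing in the labels says which embryos shared a litter, a dam or a day, so each library was treated as an independent replicate and litter effects cannot be separated from group effects.

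The authors provided 1 table per tissue, with 1 row per gene symbol and 1 column per library. Every library matched 1 column. The submitters' processing notes list kallisto 0.46.1, DESeq2 1.38.3 and the mouse build mm10, without saying which step used which. The deposited values are a normalized score, not raw counts: the authors scaled gene-level counts between libraries, removed 4 factors of unwanted variation with RUVs (k = 4 in the tables' names) and rounded the result to whole numbers. In the values, all entries were whole numbers and the upper quartile was 613 to 638 in every placenta library and 629 to 643 in every brain library. After each group of the labels was centred on its mean, 4 of the 18 remaining sample dimensions in placenta and 4 of the 17 in brain held almost no variance, whereas centring on random groups of the same sizes left 0 and 1 such dimensions. The removal therefore used the groups that are compared here, the spread within groups is smaller than it was before it, and the p-values are too small to an extent that these tables do not fix. The columns summed to 15.6e6 to 21.1e6 in placenta and 12.4e6 to 12.6e6 in brain, but sums of normalized values are not read depth. Since the depth is unknown, no counting interval or detection floor is given.

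The placenta table held 22028 gene symbols, 548 of them at 0 in every library, and the one for brain held 19533, with 74 at 0 throughout. Genes with a mean value of at least 10 over the libraries of a tissue were tested, which kept 14724 genes in placenta and 14338 in brain. Values were analysed as log2(value + 1) in R 4.3.3 with limma 3.58.1 (group means model, empirical Bayes moderation with a mean-variance trend). All 24 placenta libraries entered 1 fit with 6 group means, and all 21 brain libraries 1 fit with 4 group means. Stage contrasts averaged the sexes, sex contrasts were taken within a stage, and the sex-by-stage interaction was an F test. Each knockout was compared with WT and with each other knockout. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, separately for each contrast, and genes with an adjusted p under 0.05 were called. All tests were two-sided.

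Gene lists of cell type markers and pathways, 29 for placenta and 30 for brain, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast that had at least 3 tested genes. They were tested again with the correlation estimated from the data, and with fry. Of 354 tests of a list in a contrast, 134 passed with the preset correlation and 9 with the estimated one. By contrast, 15, 13 and 12 passed for the stages, 6, 14 and 9 for sex, 12, 6 and 10 for Sert, Tph1 and Oct3 KO against WT, and 13, 13 and 11 between knockouts; not all of them are described. List members were counted at the adjustment over all genes and again adjusted over the list alone. Genes are named by a rule. For each stage contrast and each knockout against WT, it takes the 10 largest rises and 10 largest falls among called genes with a mean of at least 100 in the higher group and no overlap between the libraries of the 2 groups; for the other contrasts it takes 5 of each. It adds up to 4 members with the smallest p from each list described, the 5 smallest p of the interaction, 6 genes of serotonin handling wherever they passed the filter (the 3 targeted genes, Tph2, Tgm2 and Maoa) and, for sex, the Y-linked genes. Symbols of predicted genes and clone names were passed over. The comparisons, lists, this rule and the tests were fixed before the data were examined, except for tests and alternatives that are named as chosen later. Positions came from GENCODE release M21 on mm10; a unique position was found for 95.5% of the placenta genes tested and 95.8% of the brain genes.

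The pipeline was tested on simulated data: with libraries drawn from each gene's mean and fitted spread and 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, 82.1% of those at 1.5-fold, 88.1% at 2-fold and 100% at 4-fold were recovered for E12.5 against E9.5. The same shares were 62.7%, 76.1% and 98.5% for sex at E12.5, 80.6%, 89.6% and 95.5% for Sert KO against WT, 74.6%, 85.1% and 98.5% for Tph1 KO against WT, and 41.8%, 59.7% and 93.9% for the interaction, with 5 to 11 false calls. The one list of 30 that was shifted was called with both correlations, and 0 of the other lists were. Genes were drawn independently of each other there, so this does not test the preset correlation where list members vary together. In 20 simulations with 4 unwanted factors and no difference between the groups, removing those factors within groups as RUVs does raised the share of genes with an unadjusted p under 0.05 from 8.49% to 14.7% for Sert KO against WT, and from 3.65% to 11.6% for sex at E12.5. Genes called at an adjusted p under 0.05 in those simulations had a median of 0 (at most 634) before and 11.5 (at most 1308) after the removal for Sert KO against WT, and of 0 (at most 37) and 4.5 (at most 792) for sex at E12.5. With 4 degrees of freedom fewer the medians were 0 and the largest counts 359 and 127.

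The alternatives tried were a pseudocount of 5, no filter on low values, median-of-ratios rescaling, quantile normalization, no mean-variance trend, residual degrees of freedom reduced by 4, runs of neighbouring embryo numbers as a correlated block, pairs of such numbers as a fixed block in placenta, fits of only the groups compared, runs of embryos left out, each library left out in turn and a minimum absolute log2 difference of 1. A covariate of Xist was planned for the brains and could not be run, because the tables used hold no Xist value. The chromatin data of the study were not analysed here.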

Results

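Whole-tissue poly(A) RNA was measured in 45 mouse libraries: 24 from WT placenta and 21 from E12.5 brain. The placentas covered E9.5, E12.5 and E17.5 with 4 female and 4 male libraries at each stage. The brains were WT (n = 5) or carried a label of 1 of 3 knockouts: Sert KO (n = 6; Sert is the serotonin transporter, encoded by Slc6a4), Tph1 KO (n = 5; tryptophan hydroxylase 1, the first enzyme of serotonin synthesis outside the brain) and Oct3 KO (n = 5; a low-affinity monoamine transporter, encoded by Slc22a3). All values are the authors' normalized expression values, given as mean ± SD over libraries, and all differences are on the log2 scale. Their read depth is unknown. Of the variance in placenta, 62.8% lay on the first principal component and 13.9% on the second, and 99.6% and 98.8% of these components' variance lay between groups. In brain the first 2 components held 14.6% and 13.2%.

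The first question was how the placenta changes between E9.5 and E12.5 (n = 8 per stage, both sexes). Prolactin-family genes on chromosome 13 went both ways: of the 25 tested, 9 rose and 12 fell (10 and 12 adjusted over the list alone), and the list did not pass with camera (adjusted p = 0.471, and 0.814 with an estimated correlation). With fry the list passed, lower at E12.5 (adjusted p = 0.00102). Prl3d1, the placental lactogen of trophoblast giant cells, dropped from 55408 ± 14621 to 844 ± 261, a 65.6-fold fall, and its neighbours Prl3d2 and Prl3d3 fell 72.8-fold and 63.7-fold. Prl7a2, a spongiotrophoblast prolactin, rose from 61.1 ± 25.4 to 9728 ± 2373, and Prl8a8 rose 86.2-fold. Pregnancy-specific glycoprotein genes and their Ceacam relatives on chromosome 7, which encode proteins secreted by trophoblast, rose by similar amounts: Ceacam14 143-fold, Psg27 130-fold (113 ± 60.9 to 13454 ± 3244), Psg18 106-fold, Psg25 104-fold, Ceacam5 88.6-fold and Ceacam12 81.7-fold. Among the placental cathepsins, proteases found only in rodent placenta, Ctsm rose 158-fold and Cts3 108-fold while Cts7 fell 31.2-fold. The other steepest falls were in Igfbpl1 (log2 difference -6.95), the keratin gene Krt84 (-6.55), the aldehyde dehydrogenase gene Aldh3a1 (-6.21), Hrc (-5.30), Gpr151 (-4.91) and the ephrin receptor gene Ephb1 (-4.70). Differences over values near 0 depend on the pseudocount: with 5 in place of 1, Igfbpl1 (0.5 ± 1.41 at E12.5), Aldh3a1 and Gpr151 differed by -4.87, -5.15 and -3.92 and Krt84, by -6.22, fell more than these. In all, 4498 genes were higher and 4801 lower at E12.5, 9299 of the 14724 tested, and the genes named so far in this comparison had adjusted p between 2.63e-09 and 9.19e-18. With a minimum absolute log2 difference of 1 the count was 2199. Which direction had more genes depended on the scaling: 4731 were higher and 4606 lower with median-of-ratios rescaling, and 5232 and 4177 with quantile normalization.

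Trophoblast markers moved by subtype between these stages. Of the 20 pregnancy-specific glycoprotein and Ceacam genes, 17 rose and 2 fell (median 5.58, adjusted p = 8.8e-11), with Psg17 and Psg19 higher by 6.24 and 4.19. Of 15 spongiotrophoblast and glycogen trophoblast markers, 10 rose and 3 fell (adjusted p = 0.000418), among the former Tpbpb (5.94), Tpbpa (4.09) and Flt1 (3.78), which encodes a VEGF receptor. Of 12 giant cell markers, 9 fell and 3 rose (adjusted p = 0.0165), and Prl4a1 fell by 2.51. With an estimated correlation, adjusted p = 0.15, 0.114 and 0.402 for these 3 lists. Adjusted over the list alone the counts were the same, with 1 more fall among the spongiotrophoblast markers.

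Genes of maternal and immune cells fell between E9.5 and E12.5. Of 17 decidual stroma markers 15 fell and 1 rose (median -1.67, adjusted p = 7.68e-07), among them Bmp2, a growth factor of decidualization (-3.84), Angpt4 (-1.91), Hoxa11 (-1.61) and the connexin gene Gja1 (-1.68). All 17 tested markers of uterine natural killer and T cells fell (adjusted p = 9.84e-07), with the granzyme genes Gzma (-4.57) and Gzmb (-2.32) and the receptor genes Ncr1 (-4.53) and Il2rb (-1.13) having the smallest p. Macrophage genes fell in 9 of 14 and rose in 2 (adjusted p = 0.0195), including C1qa (-1.11), C1qc (-1.17), Tyrobp (-1.73) and Fcer1g (-1.12). Camera with the correlation estimated gave adjusted p = 0.114, 0.19 and 0.332 for these lists, and the counts adjusted over the list alone were the same. Of 2 genes picked after the values were seen, Psap, a lysosomal protein precursor, reached 1351235 in female library 3, 6.42% of its total, and 738998 in female library 1, against 102159 to 323991 in the other 6 E9.5 libraries, and the decidual prolactin gene Prl8a2 was highest in the same 2 (352637 and 182298). These 2 genes do not show that those libraries held more maternal tissue, since Gzma was lowest in female library 3 (202, with up to 478 in the other 7).

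Steroid synthesis, blood and transport genes also shifted by E12.5. Steroid synthesis genes fell in 13 of 18 and rose in 3 (adjusted p = 0.00193), among them Star, which moves cholesterol into mitochondria (-3.70), and the enzyme genes Hsd3b6 (-3.83), Srd5a1 (-2.38) and Cyp17a1 (-2.16). Angiogenic factors fell in 13 of 19 (adjusted p = 0.00437), including Angpt2 (-2.19), Adora2b (-2.07) and the endothelial co-receptor gene Eng (-0.83), while Flt1 was the 1 that rose. Of 15 endothelial genes 12 fell (adjusted p = 0.000164), including Pecam1 (-1.09), Flt4 (-1.06) and Egfl7 (-0.79). Definitive erythroid genes rose in 10 of 11 (adjusted p = 0.0015), with the adult globins Hbb-bt, Hba-a1 and Hba-a2 up by 2.10, 2.05 and 1.94 and Ermap by 1.83. Nutrient transporter genes rose in 19 of 30 and fell in 6 (adjusted p = 0.00303), with Slc7a2 up by 2.46, the fatty acid transporter Cd36 by 1.77, Slc38a4 by 1.49 and Slc38a1 by 0.86. Ribosomal protein genes fell in 42 of 47 (adjusted p = 7.46e-09), by a median of -0.28, Rps2 (-0.69), Rpl13 (-0.59), Rplp0 (-0.49) and Rpsa (-0.47) having the smallest p. Under an estimated correlation, adjusted p = 0.114, 0.114, 0.19, 0.332, 0.262 and 0.364 in the order given. With adjustment within each list, 43 ribosomal genes fell and the other counts were the same.

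Between E12.5 and E17.5 the placenta lowered its cell cycle genes and raised another set of secreted trophoblast products. All 30 cell cycle genes fell (median -3.14, adjusted p = 1.84e-22), and this list also passed with an estimated correlation (adjusted p = 0.0227). Ccna2, a cyclin of S and G2 phase, went from 514 ± 54.2 to 21.4 ± 3.62, and Mki67 (-4.31), Ccnb2 (-4.19) and the replication helicase gene Mcm5 (-4.08) fell alike. Psg16 climbed from 8777 ± 2491 to 504752 ± 129561, a 58.3-fold rise that made it the highest gene of every E17.5 library. The prolactin-family genes Prl3a1, Prl8a6 and Prl5a1 rose 411-fold, 122-fold and 49.3-fold, and the cathepsin gene Cts6 rose 340-fold, from 72.4 ± 30.3 to 24170 ± 7527. Also among the 10 largest rises were Doxl2 (7.34), Scn9a, which encodes a sodium channel (6.70), the clotting factor gene F11 (5.69), Psg26 (5.62) and Ly6g6c (5.29). With a pseudocount of 5, Prl3a1 rose 268-fold and Scn9a 48.7-fold (104-fold with 1).

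The largest falls at E17.5 against E12.5 were in the embryonic globin genes Hbb-y (-8.82), Hba-x (-8.06) and Hbb-bh1 (-7.74), products of the primitive red cells of the early embryo. Hbb-y declined from 4042 ± 2114 to 8.25 ± 5.23. Dio3, which inactivates thyroid hormone, fell 70.5-fold to 48.1 (24 to 78 over 8 libraries), and Hsd11b2, which inactivates glucocorticoids, fell 32.4-fold. Ceacam9 (-5.85), Utf1 (-4.53), the imprinted growth gene Phlda2 (-4.42) and Prr9 (-4.42) completed the list with Ccna2. A pseudocount of 5 gave -8.20, -7.29 and -5.85 for the 3 globin genes and -3.57 for Prr9. In total 4880 genes were higher and 5237 lower, 10117 of 14724, and the named genes had adjusted p from 4.55e-08 to 1.82e-19. The count was 2261 with a minimum absolute log2 difference of 1, and with median-of-ratios rescaling 5187 genes were higher and 4920 lower.

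Gene groups divided in the same interval. Of 20 pregnancy-specific glycoprotein and Ceacam genes 19 rose and 1, Ceacam9, fell (adjusted p = 8.96e-07), with Psg23 up by 4.09. Cathepsins rose in 6 of 8 and fell in 2 (adjusted p = 0.0273), Ctsq by 4.40, Cts3 by 2.60 and Ctsj by 1.94. All 10 tested yolk sac endoderm genes rose (adjusted p = 5.46e-05), with the lipoprotein genes Apoa1 up by 3.79 (smallest p), Apob by 3.60, Apoa4 by 3.58 and the iron carrier gene Trf by 2.37. Nutrient transporter genes rose in 24 of 30 and fell in 3 (adjusted p = 2.88e-05), among them the amino acid transporter genes Slc1a4 (1.83), Slc7a1 (1.63) and Slc3a2 (0.79) and Cd36 (1.48). Macrophage genes rose in 11 of 14 and fell in 3 (adjusted p = 0.0295), including C1qc (1.40), C1qa (1.36), Csf1r (1.05) and Cd68 (0.60). Once the correlation was estimated, adjusted p = 0.327, 0.379, 0.263, 0.195 and 0.379 for these 5 lists, whose counts adjusted over the list alone were the same.

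Other groups fell from E12.5 to E17.5. The 3 embryonic globins all fell (adjusted p = 0.00189). Natural killer and T cell markers fell in 13 of 17 (adjusted p = 5.46e-05), with the perforin gene Prf1 (-4.26), Gzmc (-4.16), Klrg1 (-4.14) and Gzmd (-4.12) having the smallest p. Decidual stroma markers fell in 10 of 17 and rose in 4 (adjusted p = 0.0495), Hand2 (-1.89), Hoxa11 (-1.24), Hoxa10 (-1.17) and Gja1 (-1.17) among the former. All 47 tested ribosomal protein genes fell (median -0.70, adjusted p = 3.5e-18), for instance Rpsa (-1.23), Rps2 (-1.07), Rps11 (-0.99) and Rpl14 (-0.95). Nuclear genes of oxidative phosphorylation fell in 29 of 32 (median -0.54, adjusted p = 1.26e-09), for instance Sdhb (-0.93), Atp5a1 (-0.82), Atp5o (-0.77) and Cox5a (-0.74). With an estimated correlation, adjusted p = 0.263, 0.327, 0.488, 0.263 and 0.263 in this order. Over the list alone, 11 decidual and 30 oxidative phosphorylation genes fell and the other counts were the same.

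Over the whole span from E9.5 to E17.5, 5452 genes rose and 6177 fell, 11629 of 14724, or 4217 at a minimum absolute log2 difference of 1. Here too the balance turned, to 5816 and 5797 with median-of-ratios rescaling and 5800 and 5773 with quantile normalization. With the pseudocount of 1, Cts6 rose 1076-fold and Prl8a6 1006-fold, followed by Prl3a1 (888-fold), F11 (801-fold), Ceacam12 (799-fold), Prl8a8 (795-fold), Psg26 (770-fold), Psg21 (712-fold), Psg28 (690-fold) and Psg23 (686-fold). Hbb-bh1 fell 529-fold, Krt84 477-fold, Ceacam9 from 4115 ± 1064 to 21.8 ± 10.9, Hba-x 178-fold, Dio3 174-fold, Hbb-y 138-fold, Hsd3b6 125-fold, Aldh3a1 and Hephl1 124-fold and Guca2a 123-fold. The size and order of these folds depend on the pseudocount where a mean is near 0, as for F11 and Prl3a1 (4.0) at E9.5 and Hbb-bh1 at E17.5. With a pseudocount of 5, F11 and Prl3a1 rose 260-fold and 387-fold, less than the other 8 (634-fold to 900-fold, Prl8a6 the most). Hbb-bh1 then fell 142-fold, less than Krt84 (232-fold), Ceacam9 (160-fold) and Dio3 (159-fold), and Hba-x, Hbb-y, Guca2a and Aldh3a1 fell 105-fold, 89.5-fold, 75.2-fold and 44.8-fold. These genes had adjusted p of 1.74e-11 or smaller. Pregnancy-specific glycoprotein and Ceacam genes rose in 18 of 20 and fell in 2 (adjusted p = 3.82e-09), Psg16 by 9.34, Psg18 by 8.14, Psg17 by 7.98 and Psg19 by 5.74. All 30 cell cycle genes fell (adjusted p = 7.7e-16), with Rrm2 (-4.71), Mcm5 (-4.50), Ccna2 (-4.49) and Mcm4 (-2.21) having the smallest p. All 17 natural killer and T cell markers fell (adjusted p = 4.09e-07), among them Klrg1 (-6.28), Prf1 (-6.21), Gzmb (-6.14) and Gzmc (-5.69), and 15 of 17 decidual markers fell and 2 rose (adjusted p = 8.89e-05), among the former Bmp2 (-4.59), Hand2 (-3.88), Hoxa11 (-2.85) and Gja1 (-2.84). Nutrient transporter genes rose in 23 of 30 and fell in 4 (adjusted p = 1.42e-05), Cd36 by 3.25, Slc7a2 by 3.13, Slc38a4 by 2.30 and Slc7a1 by 2.16. Syncytiotrophoblast genes, of the layer that separates maternal from fetal blood, rose in 12 of 14 and fell in 1 (adjusted p = 0.017), with Snap91 up by 2.37, Slco2a1 by 2.12, the fusion gene Synb by 1.82 and Slc16a3 by 0.88. Camera with the correlation estimated gave adjusted p = 0.233, 0.1, 0.233, 0.233, 0.172 and 0.112 for these 6 lists, and the counts adjusted over the list alone were the same.

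**Figure D1:**
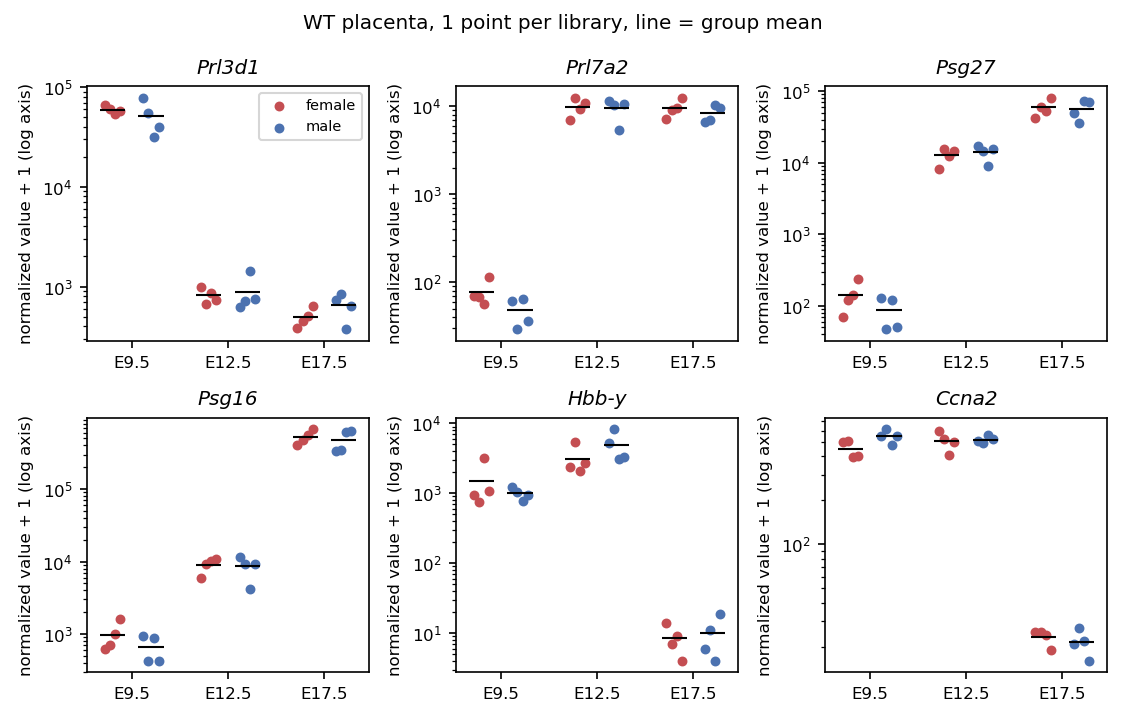
Normalized values plus 1 (log axes) of 6 genes in the 24 WT placenta libraries, by stage and sex; each point is 1 library and each line a group mean. Prl3d1 was highest at E9.5, Prl7a2 rose by E12.5, Psg27 and Psg16 rose at both steps, and Hbb-y and Ccna2 fell to means of 8.25 and 21.4 at E17.5.

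Genes that make, carry or degrade serotonin were followed in every comparison, since the study concerns placental serotonin. Tph1 was close to 0 at E9.5 (0.25 ± 0.5 in males and 1.25 ± 1.5 in females), 12 ± 7.96 and 5.5 ± 0.577 at E12.5, and 244 ± 54.9 and 178 ± 128 at E17.5, a rise of 4.50 from E12.5 (adjusted p = 1.18e-08), or 3.88 with a pseudocount of 5. Slc6a4 dipped, falling by 0.92 from E9.5 to E12.5 (adjusted p = 0.000123) and rising by 1.15 to E17.5 (adjusted p = 6.12e-06). It averaged 54 to 56.8 at E12.5 and between 99.8 and 143 in the groups of the other stages. Slc22a3 rose by 0.94 to E12.5 and by 0.33 to E17.5 (adjusted p = 6.84e-06 and 0.0497), from 48.2 to 92.4 and then 115. Maoa, the enzyme that degrades serotonin, rose by E12.5 (1.06, adjusted p = 7.07e-10) and then differed by -0.02 (adjusted p = 0.824). Tgm2, the transglutaminase that attaches serotonin to proteins, was abundant throughout, with group means from 18200 to 24776, and rose by 0.19 and fell by 0.31 at the 2 steps (adjusted p = 0.00901 and 0.000117). Over the whole span Tph1 rose by 6.92 (5.03 with a pseudocount of 5), Slc22a3 by 1.27 and Maoa by 1.04 (adjusted p = 3.75e-12, 4.06e-08 and 3.27e-10), whereas Slc6a4 (0.23, adjusted p = 0.233) and Tgm2 (-0.12, adjusted p = 0.0844) did not pass. Of the 19 tested genes of serotonin and monoamine handling, 7 rose and 6 fell to E12.5 (adjusted p = 0.962), with Tdo2 (-3.30), Slc6a2 (-1.33) and Tgm1 (-0.51) lower. To E17.5, 13 rose and 3 fell (adjusted p = 0.0295), with the serotonin receptor genes Htr1d (3.68) and Htr2b (2.22) and the vesicular transporter gene Slc18a2 (1.65) higher and the tryptophan-degrading Tdo2 lower (-2.58). Under an estimated correlation, adjusted p = 0.992 and 0.19, and the counts adjusted over the list alone were the same. None of Tph1, Slc6a4, Slc22a3, Maoa and Tgm2 passed the test for sex at any stage (adjusted p from 0.285 to 0.973).

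The largest differences between male and female placentas (n = 4 each per stage) were in Y-linked genes. At E9.5 11 genes were called, 5 higher in males and 6 lower; at E12.5 55 (22 and 33); at E17.5 36 (19 and 17). The Y-linked RNA helicase gene Ddx3y was 285 ± 126 in males and 5.25 ± 4.11 in females at E9.5, 761 (603 to 927) and 3.0 ± 2.0 at E12.5, and 688 ± 142 and 5.5 ± 3.70 at E17.5. Eif2s3y was 67.8 ± 29.7 in males at E9.5 against 0.25 ± 0.5 in females, and was listed at 0 in all 4 females at E12.5 and at E17.5, with male means of 80.2 ± 17.4 and 137 ± 17.8. The histone demethylase genes Kdm5d (0.76, 1.05 and 0.85 over the stages) and Uty (2.88 at E12.5 and 2.18 at E17.5) were also higher in males; Uty did not pass at E9.5 (0.80, adjusted p = 0.2). Females also had Kdm5d values of 144.5 ± 20.1 to 259 ± 30.3. The 4 Y-linked genes passed as a list at each stage (adjusted p = 7.69e-16, 4.29e-25 and 3.15e-21), with 3, 4 and 4 members called and all 4 adjusted over the list alone, and again with an estimated correlation (adjusted p = 0.000164, 7.13e-06 and 2.33e-05).

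X-linked genes that escape inactivation were lower in males as a list. Of the 4 tested (Kdm6a, Kdm5c, Eif2s3x and Ddx3x; Xist is not in the table), 0 were called at E9.5, 1 at E12.5 and 2 at E17.5, and 2, 3 and 3 adjusted over the list alone; 3 of the 4 had an unadjusted p under 0.05 at E9.5. Eif2s3x differed by -0.23, -0.50 and -0.50 and Kdm5c by -0.23, -0.29 and -0.39, of which Eif2s3x passed at E12.5 and E17.5 (adjusted p = 0.00021 and 0.000241) and Kdm5c at E17.5 (adjusted p = 0.0167). The list had adjusted p = 0.00389, 0.00125 and 0.00047, and with an estimated correlation adjusted p = 0.157, 0.0704 and 0.0419. The X-linked sugar transferase gene Ogt was lower in males at E12.5 (-0.67) and E17.5 (-0.64), and the X-linked Maob, which degrades monoamines, was lower at E12.5 (42.5 ± 3.32 against 116.5 ± 23.5, adjusted p = 0.0468).

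Autosomal genes named by the rule were few. At E9.5 Cdk18 (-1.05), Nudt12 (-1.0), Sgms1 (-0.49) and Lzic (-0.46) were lower in males (adjusted p from 0.00386 to 0.0435). At E12.5 Fam188a (0.61) was higher and Abca9 (-0.93), Itpr2 (-0.80) and Disp2 (-0.67) lower, and the processed pseudogene Pgam1-ps2 was 6901 ± 1709 against 1393 ± 1059. Reads of the latter cannot be separated from its parent gene here. At E17.5 Slc22a21 (0.90) was higher and the vessel-destabilizing factor gene Angpt2 (-0.67), Ten1 (-0.49) and Gmnn (-0.47) lower. Yolk sac endoderm genes passed as a list, lower in males at E9.5 (median -0.88, adjusted p = 0.000148) and E12.5 (-1.41, adjusted p = 5.33e-09), with 0 of 10 members called at either stage, 6 and 7 at an unadjusted p under 0.05, and 0 and 7 adjusted over the list alone; Rbp4 differed by -1.02 (adjusted p = 0.235) and Ttr by -1.87 (adjusted p = 0.0517), respectively. Pregnancy-specific glycoprotein and Ceacam genes at E9.5 (median -0.53, adjusted p = 0.000148, 0 of 20 called and 5 at an unadjusted p), endothelial genes (-0.24, adjusted p = 1.03e-05, 0 of 15, 6 unadjusted) and definitive erythroid genes (0.56, adjusted p = 5.2e-05, 0 of 11, 4 unadjusted) at E12.5, and mitochondrially encoded genes at E17.5 (0.20, adjusted p = 8.93e-06, 0 of 12, 5 unadjusted) passed likewise. At E17.5 the yolk sac list passed in the opposite direction, higher in males (median 0.51, adjusted p = 0.0344, 0 of 10 members called, 1 unadjusted and 0 adjusted over the list alone; adjusted p = 0.78 with an estimated correlation), but not without female library 1 or male library 1 of that stage (adjusted p = 0.265 and 0.291). Adjusted over the list alone they had 0, 3, 3 and 4 members called. Once the correlation was estimated, adjusted p = 0.524 and 0.0726 for the yolk sac list and 0.753, 0.152, 0.249 and 0.445 for the others, so none of these passed. The sex counts depended on single libraries and on the degrees of freedom assumed: with 1 library left out they ranged from 3 to 99, 20 to 72 and 15 to 151, and with 4 degrees of freedom fewer they were 2, 9 and 8.

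The difference between the sexes itself differed between stages for 9 of 14724 genes. Kng1, which encodes the bradykinin precursor, was lower in males at E12.5 (-1.72) and differed by -0.40 at E9.5 and 0.54 at E17.5 (F = 31.0, adjusted p = 0.00622). Dpy19l4 differed by -0.04, -0.16 and 0.59 over the stages (adjusted p = 0.0152). Btk, a kinase of B cells and macrophages, differed by 0.08, -1.82 and 0.96, Nudt12 by -1.0, 0.10 and 0.17, and Pgam1-ps2 by -1.40, 2.61 and -1.46 (adjusted p = 0.0302 for each). With 4 degrees of freedom fewer, limma called 0 genes in this test, with 1127 at an unadjusted p under 0.05, and with 1 library left out it called 2 to 27.

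The brain libraries were first checked at the 3 targeted genes. Slc6a4 (chromosome 11, 76998603 to 77032340, plus strand) was 13 ± 6.16 in WT brains (n = 5), 13.8 ± 4.38 in Tph1 KO, 9.0 ± 2.92 in Oct3 KO and 139 ± 33.4 in the libraries labelled Sert KO (n = 6, range 93 to 184). It was thus higher, not lower, in all 6 libraries with that label (log2 difference 3.38, adjusted p = 1.46e-07); the labels do not state which part of the gene was altered. Tph1 (chromosome 7, 46644641 to 46672537, minus strand) was low: 2.4 ± 1.14 in WT and 8.4 ± 5.77 in Tph1 KO, below the filter for testing and not lower in the knockout. Slc22a3 (chromosome 17, 12418960 to 12507704, minus strand) was listed at 0 in all 5 Oct3 KO libraries, against 2.4 ± 2.30 in WT, 4.0 ± 2.76 in Sert KO and 3.2 ± 2.28 in Tph1 KO. It was above 0 in 14 of the 16 other brains and in 0 of 5 Oct3 KO brains (Fisher's exact test, two-sided, p = 0.00103; against WT alone, 4 of 5, p = 0.0476), a test chosen after the values were seen, on values whose adjustment had used the groups. Tph2, the brain form of the synthetic enzyme, averaged 2.8 to 8.33 in the 4 groups and was not tested either. Maoa was between 460 and 480 in every group and Tgm2 between 147 and 192, and neither passed in any brain comparison (adjusted p from 0.156 to 0.989). Slc6a4 did not pass in Tph1 KO or Oct3 KO against WT (adjusted p = 0.924 and 0.528) or between these 2 (adjusted p = 0.359). At values this low and an unknown depth Slc22a3 cannot be called absent. The names Sert KO, Tph1 KO and Oct3 KO stand for labels throughout.

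**Figure D2:**
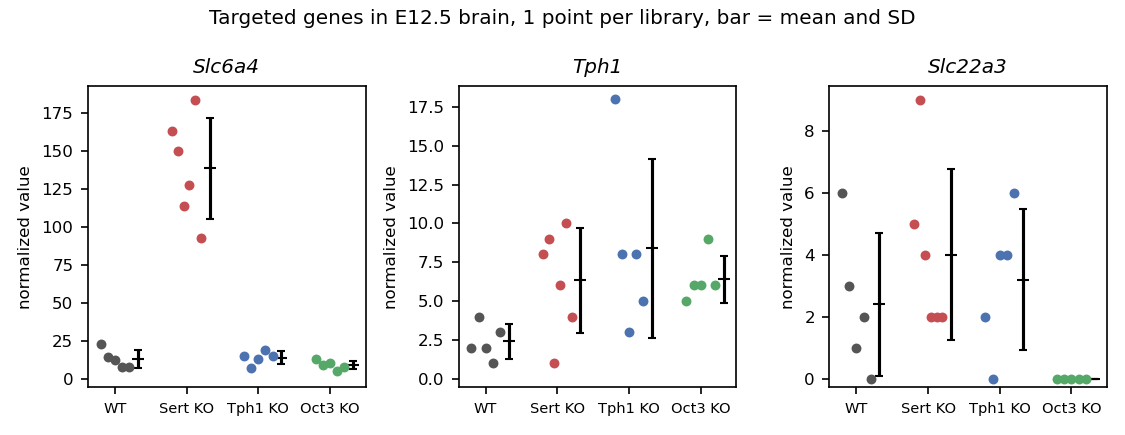
Normalized values of the 3 targeted genes in the 21 E12.5 brain libraries by genotype label; each point is 1 library, the bars give the mean and SD. The 6 libraries labelled Sert KO lie between 93 and 184 for Slc6a4, above all others, and the 5 Oct3 KO libraries lie at 0 for Slc22a3.

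In brains labelled Sert KO 15 of 23 markers of postmitotic neurons were higher than in WT and 23 of 30 cell cycle genes lower. Both lists passed with the preset correlation (adjusted p = 2.41e-10 and 4.42e-16) but not with an estimated one (adjusted p = 0.195 and 0.0515). Apart from Slc6a4, the largest rises were in Slc7a4 (35.8 ± 18.3 in WT, 158 ± 93.4 in Sert KO), the cell polarity gene Crb1 (46.0 ± 12.1 to 140 ± 15.9), the folate enzyme gene Aldh1l1 (1.60), the glutamate receptor gene Grm5 (1.44), the neuronal chromatin remodeller gene Chd5 (1.16), Aldoc (1.14), Ablim3 (1.13), the cortical neuron transcription factor gene Neurod6 (1247 ± 416 to 2624 ± 613) and Entpd4 (1.05). The largest falls were in Qser1 (-1.98), the embryonic globin gene Hbb-bh1 (2328 ± 539.5 to 975 ± 618), Wdfy1 (-1.10), Krcc1 (-1.08), the complement regulator gene Cd59a (-1.0), the iron importer gene Slc25a37 (-0.77) and the fatty acid desaturase gene Scd1 (-0.61). Neighbouring genes on chromosome 17 fell together: Dynlt1b, a dynein light chain gene (2417 ± 78.9 to 1178 ± 99.2), Tmem181a (-0.96) and the pseudogene Tmem181b-ps (-1.23). In all 1985 of 14338 genes were called, 1111 higher and 874 lower, and 125 at a minimum absolute log2 difference of 1. The count was 1187 without WT library 3, 897 with 4 degrees of freedom fewer, 3263 with embryos 716 to 718 alone and 385 with embryos 788 to 790 alone. The sex of these brains is not given, and Y-linked genes differed widely within groups and were spread unevenly over the labels. Ddx3y was 2575, 2213, 1111, 2090, 1230 and 29 in the Sert KO libraries in order. It was 25, 47, 1839, 10 and 1396 in the WT libraries and at most 792 in Oct3 KO. Apparent sex is therefore partly confounded with the label. With the Y-linked level as a covariate, chosen after the data were seen, the count was 2167.

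Cell cycle genes fell in 23 of 30 (median -0.27, adjusted p = 4.42e-16), with Aurkb (-0.45), Ccnb1 (-0.38), Rrm2 (-0.36) and Ccna2 (-0.30) having the smallest p. Of 14 proneural and intermediate progenitor genes 8 fell (median -0.35, adjusted p = 1.04e-07), including Neurog1, which commits cells to a neuronal fate (-0.56), the Notch ligand genes Dll3 (-0.51) and Dll1 (-0.41), and Btg2 (-0.39). With an estimated correlation, adjusted p = 0.0515 for both lists. Markers of postmitotic neurons rose in 15 of 23 (median 0.28, adjusted p = 2.41e-10), including the microtubule protein gene Mapt (0.69), Syt1 (0.51), Rbfox3 (0.36) and Stmn2 (0.29). Genes of synapses and ion channels rose in 21 of 33 and fell in 1 (median 0.40, adjusted p = 1.82e-12), including the glutamate receptor genes Grin1 (0.86) and Gria1 (0.75) and the vesicle gene Syt4 (0.70). Camera with the correlation estimated gave adjusted p = 0.195 for neurons and adjusted p = 0.118 for synapses. With adjustment within each list, 26 cell cycle genes fell, 11 progenitor genes fell and 1 rose, 18 neuronal genes rose, and 25 synaptic genes rose and 1 fell.

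By transmitter, glutamatergic neuron genes rose in 7 of 14 and fell in 1 (median 0.46, adjusted p = 4.79e-05), with Neurod6, Grin2b (0.97), Neurod2 (0.96) and Bcl11b (0.48) having the smallest p, and this list passed with an estimated correlation too (adjusted p = 0.00766). Of the serotonin and monoamine handling genes 3 of 12 rose, Slc6a4, the receptor gene Htr7 (0.95) and the transporter gene Slc29a4 (0.32), with Htr5a at 0.72 (adjusted p = 0.0539): the list had adjusted p = 0.000243 and, with an estimated correlation, adjusted p = 0.0168. Without Slc6a4 itself, a test chosen after the data were seen, 2 of 11 rose (5 adjusted over the list alone), with adjusted p = 0.00565 and, with an estimated correlation, adjusted p = 0.0515. GABAergic neuron genes rose in 6 of 17 (adjusted p = 0.000158), such as Lhx6 (1.12), Dlx6 (1.09), Sst (0.52) and Slc32a1 (0.30), and axon guidance genes rose in 10 of 38 and fell in 1 (adjusted p = 0.000243), such as Plxna4 (0.61), Nrp1 (0.47), Plxna2 (0.32) and Efnb3 (0.30). Under an estimated correlation, adjusted p = 0.201 for each of these 2 lists. Telencephalon genes rose in 6 of 14, also adjusted over the list alone, including Dlx1 (1.19), Dlx2 (1.02) and Tbr1 (0.76); the list had adjusted p = 0.0339 and, with an estimated correlation, adjusted p = 0.516, and did not pass without WT library 5 or without Sert KO library 3. Over the list alone, 8 glutamatergic genes rose and 1 fell, 6 serotonin genes and 9 GABAergic genes rose, and 12 guidance genes rose and 2 fell.

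Markers of other cells moved with the Sert KO label as well. Of 12 choroid plexus genes 2 rose, Aqp1 (0.62) and Enpp2 (0.41), and 1 fell, Otx2 (-0.53), while Ttr differed by 0.68 (adjusted p = 0.0863); the list had adjusted p = 0.0172 and, with an estimated correlation, adjusted p = 0.43. Embryonic globins fell in 2 of 3, Hbb-bh1 (-1.51) and Hba-x (-0.81), while Hbb-y differed by -0.41 (adjusted p = 0.292). Definitive erythroid genes fell in 5 of 14 and rose in 1, with the red cell membrane genes Rhag (-1.78), Rhd (-1.40) and Spta1 (-1.18) lower and the adult globin Hbb-bs higher (0.97). These 2 lists had adjusted p = 0.027 and adjusted p = 0.0155 (with an estimated correlation, adjusted p = 0.413 and adjusted p = 0.52). Adjusted over the list alone, 3 choroid plexus genes rose and 1 fell, 2 embryonic globins fell, and 7 definitive erythroid genes fell and 1 rose.

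**Figure D3:**
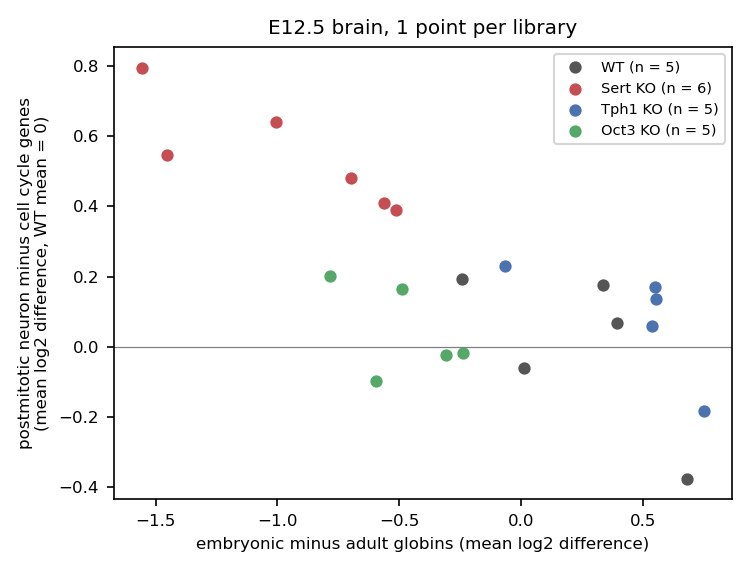
Each of the 21 brain libraries (1 point each, coloured by genotype label) by the mean log2 difference of embryonic minus adult globins (horizontal) and of postmitotic neuron minus cell cycle genes, relative to the WT mean (vertical). The 6 libraries labelled Sert KO lie at 0.390 to 0.795 vertically and at -0.513 to -1.56 horizontally.

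Brains labelled Tph1 KO differed from WT in 81 of 14338 genes, 30 higher and 51 lower. Among genes not subject to shared reads, Pop4, a subunit of an RNA-processing ribonuclease, dropped from 869 ± 31.5 to between 218 and 300 (adjusted p = 1.88e-11), and Irak1bp1 (-1.03), Bcl2l12 (-1.02), Myo7a (-0.78), the glycosylation gene Alg8 (-0.77) and the neuronal transcription factor genes Neurod6 (-0.89) and Neurod2 (-0.72) fell. Hddc3 rose from 9.4 ± 5.60 to 116 ± 40.3, Crb1 to 158 ± 30.8 and the X-linked ubiquitin ligase gene Mid1 from 942 ± 126 to 2340 ± 254, and Klf10 (0.77), Spon1 (0.76), Zfp940 (0.72), Stat2 (0.68), Prcp (0.62) and Fndc3c1 (0.61) were higher too. Rps13 (2645 ± 255 to 565 ± 564), Rps13-ps2 (-6.14) and Hmgb1-ps3 (-0.60) fell and Rps13-ps1 rose (2.8 ± 3.70 to 843 ± 632). Reads of such nearly identical copies can be assigned to any of them, so these differences are uncertain. The count was 40 without WT library 3, 48 and 52 without Tph1 KO libraries 2 and 5, 136 without Sert KO library 5, and 19 with 4 degrees of freedom fewer.

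In Tph1 KO 6 lists passed. Of 14 glutamatergic neuron genes 2, Neurod6 and Neurod2, fell (median -0.26, adjusted p = 0.0282), with Bcl11b at -0.35 (adjusted p = 0.0609) and Satb2 at 0.59 (adjusted p = 0.212), and of 14 telencephalon genes 2, Neurod6 and the forebrain patterning gene Lhx2 (-0.42), fell (adjusted p = 0.00978), with Gsx2 at -0.58 (adjusted p = 0.169) and Foxg1 at -0.66 (adjusted p = 0.395). With limma, 0 of 14 definitive erythroid genes were called (median 0.46, 5 at an unadjusted p under 0.05, list adjusted p = 0.00112) and 0 of 48 ribosomal protein genes (median -0.08, 8 unadjusted, list adjusted p = 5.28e-05), with Gypa at 0.80 (adjusted p = 0.241) and Rps23 at -0.23 (adjusted p = 0.217). Likewise 0 of 13 mitochondrially encoded genes (median -0.15, 2 unadjusted, list adjusted p = 0.00451) and 0 of 31 nuclear oxidative phosphorylation genes (median -0.07, 8 unadjusted, list adjusted p = 0.000709) were called; the former list did not pass with quantile normalization (adjusted p = 0.103) or without Tph1 KO library 5 (adjusted p = 0.0717). Once the correlation was estimated, adjusted p = 0.332 for the glutamatergic list and adjusted p = 0.74 for the others. With adjustment within each list, 1 glutamatergic gene rose and 3 fell, 3 telencephalon genes fell, and 0 members of the other 4 passed.

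Brains labelled Oct3 KO differed from WT in 271 genes, 124 higher and 147 lower, or 139 and 123 with median-of-ratios rescaling and 137 and 122 with quantile normalization. Prkaa1, a catalytic subunit of AMP-activated kinase, was 25.6 ± 25.7 against 1301 ± 1011, Gfer, a sulfhydryl oxidase gene, 6.0 ± 4.69 against 152 ± 47.0, and Efcab7 2.8 ± 2.95 against 112 ± 36.2. Prkaa1 ranged from 382 to 2905 in WT and 14 to 1043 in Tph1 KO, so its fall is uncertain. The patterning genes Olig3 (-2.49) and Gbx2 (-1.76), expressed in the thalamic region among others, fell, as did Tagap1 (-1.86), Caskin1 (-0.99), Cd59a (-0.93), Zfp277 (-0.88) and Zfp40 (-0.83). The glyoxalase gene Glo1 rose from 1089 ± 56.8 to 2076 ± 130, Crb1 to 125 ± 18.2, Neurod6 to 2254 ± 190, and Thbs2 (0.92), Sphkap (0.83), Emp1 (0.83), Vgll3 (0.82) and the synaptic vesicle gene Sv2b (0.78) rose too. Hmga1-rs1 (148 ± 267 to 2567 ± 572) and Rps2-ps10 (66 ± 16.5 to 3154 ± 270) also rose, but both can take up reads of near-identical parent genes. The count was 144 and 164 without Oct3 KO libraries 2 and 1, 179 without WT library 5, 75 higher and 87 lower without WT library 3, 86 with 4 degrees of freedom fewer, and 74 or 78 with either run of embryo numbers alone.

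In Oct3 KO 10 lists passed with the preset correlation and 0 with an estimated one. Of 12 choroid plexus genes 3 fell, Kcnj13 (-1.28), Kcne2 (-1.10) and Clic6 (-0.72), while Ttr differed by -0.88 (adjusted p = 0.116), and the list had adjusted p = 0.000158. Of 10 diencephalon and hypothalamus genes 2, Olig3 and Gbx2, fell (adjusted p = 0.0304), with Tcf7l2 at -0.98 (adjusted p = 0.192) and Otp at -1.20 (adjusted p = 0.226). Glutamatergic neuron genes rose in 3 of 14, Neurod6 (0.91), Neurod2 (0.72) and Bcl11b (0.36), and 1, Lhx5, fell (-0.50; list adjusted p = 0.00342). Axon guidance genes rose in 3 of 38, Plxna4 (0.69), Epha5 (0.46) and Plxna2 (0.39), with Efnb2 at 0.23 (adjusted p = 0.0794; list adjusted p = 0.000158), and of 16 mesenchyme genes 1 rose, Dcn (0.33), with Col1a2 at 0.38 (adjusted p = 0.156; list adjusted p = 3.69e-06). With an estimated correlation, adjusted p = 0.0648 for the glutamatergic list, adjusted p = 0.448 for diencephalon and adjusted p = 0.369 for the other 3. Over the list alone, 5 choroid plexus and 4 diencephalon genes fell, 3 glutamatergic genes rose and 1 fell, 9 guidance genes rose and 2 fell, and 4 mesenchyme genes rose. The other 5 lists had 1 or 0 members called by limma, with the number at an unadjusted p under 0.05 given as unadjusted: telencephalon (median 0.21, 1 of 14, Neurod6, 2 unadjusted; list adjusted p = 0.0334), definitive erythroid (-0.50, 0 of 14, 5 unadjusted; 0.0224), dopaminergic and noradrenergic neurons (-0.28, 0 of 7, 3 unadjusted; 0.0431), synapses and ion channels (0.05, 0 of 33, 5 unadjusted; 0.0304) and nuclear oxidative phosphorylation (-0.06, 0 of 31, 5 unadjusted; 0.021). These 5 had adjusted p from 0.415 to 0.774 with an estimated correlation, and 1, 0, 2, 0 and 0 members adjusted over the list alone; each also failed without at least 1 single library.

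Called genes lay near the targeted gene in Oct3 KO and were spread over the chromosome of the targeted gene in Tph1 KO. In Oct3 KO 29 of the 260 genes tested within 20 Mb of Slc22a3 were called (11.2%), 8 higher and 21 lower, against 1.71% of genes on other chromosomes (odds ratio 7.21, 95% confidence interval 4.62 to 10.9, Fisher's exact test, two-sided, adjusted p = 1.06e-13 over 9 tests) and 5 of 389 on the rest of chromosome 17 (odds ratio 9.61 against the rest, interval 3.61 to 32.3, adjusted p = 1.45e-07 over 3 tests). In Tph1 KO 10 of 293 genes within 20 Mb of Tph1 were called (3.41%), against 0.393% on other chromosomes (odds ratio 8.96, interval 4.01 to 18.1, adjusted p = 3.58e-06), and so were 18 of 712 (2.53%) on the rest of chromosome 7 (odds ratio 1.36 against the rest, interval 0.554 to 3.16, adjusted p = 0.527). By distance from Tph1 the shares were 3.1% within 10 Mb, 3.66% from 10 to 20, 1.85% from 20 to 40, 4.35% from 40 to 80 and 0.508% beyond. Around Slc6a4 in Sert KO 67 of 450 genes were called (14.9%), against 13.9% on other chromosomes (odds ratio 1.09, interval 0.822 to 1.42, adjusted p = 0.533). Pop4, Bcl2l12, Alg8, Myo7a, Hddc3, Spon1, Zfp940 and Prcp lie on chromosome 7, and Gfer, Glo1, Thbs2, Tagap1, Caskin1 and Zfp40 on chromosome 17. Without chromosome 7, 53 genes remained in the Tph1 KO count.

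Whether the groups labelled as knockouts differed from each other was tested directly. Brains labelled Sert KO and Tph1 KO differed in 2445 genes, 1400 higher in Sert KO. Beyond Slc6a4 (3.26), the largest differences were in Neurod6 (2624 ± 613 against 656 ± 135), Grm5 (1.79) and Aldoc (1.68), higher in Sert KO, and in Hddc3 (-4.59), Hbb-bh1 (-2.05), Trim10 (-1.57) and Slc25a37 (-1.40), lower, with Rps13 (2.91) and Rps13-ps1 (-7.61) again uncertain. A pseudocount of 5 gave -3.48 for Hddc3 and -6.38 for Rps13-ps1. Glutamatergic neuron genes were higher in Sert KO in 10 of 14 and lower in 1 (median 0.77, adjusted p = 3.41e-06), Neurod2 by 1.68, Tbr1 by 1.10 and Bcl11b by 0.84, and passed with an estimated correlation (adjusted p = 0.0024). Cell cycle genes were lower in 22 of 30 (adjusted p = 2.55e-15), Mki67 (-0.34), Rrm2 (-0.35), Aurkb (-0.32) and Ccnb1 (-0.32) having the smallest p. Choroid plexus genes were higher in 7 of 12 and lower in 1 (adjusted p = 0.00128), Ttr by 1.17, Aqp1 by 0.76 and Enpp2 by 0.49, with Otx2 lower (-0.62), and definitive erythroid genes lower in 9 of 14 (adjusted p = 1.05e-05), Rhag (-2.02), Spta1 (-1.81), Gypa (-1.51) and Ermap (-1.39) among them. Camera with the correlation estimated gave adjusted p = 0.0597, adjusted p = 0.243 and adjusted p = 0.245 for these 3. Adjusted over the list alone, 10 and 1 glutamatergic, 27 cell cycle, 8 and 1 choroid plexus and 9 erythroid genes passed. The whole count was 1198 with 4 degrees of freedom fewer and 1459 in a fit of these 2 groups alone.

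Brains labelled Sert KO and Oct3 KO differed in 1593 genes, 1040 higher and 553 lower in Sert KO, or 897 and 777 with median-of-ratios rescaling and 789 and 699 with quantile normalization. Prkaa1 (5.91), Gfer (4.57), Slc6a4 (3.82), the hypothalamic gene Otp (144 ± 94.9 against 19.6 ± 6.58) and Ksr2 (2.34) were higher in Sert KO, and Dynlt1b (1178 ± 99.2 against 2719 ± 253.5) and Tmem181b-ps (-1.63) lower, as were the uncertain copies Hmga1-rs1 (-8.22), Rpl3-ps1 (-6.60) and Rps2-ps10 (-5.13). With a pseudocount of 5 the difference was 3.79 for Gfer, -7.48 for Hmga1-rs1 and -5.59 for Rpl3-ps1. Choroid plexus genes were higher in 9 of 12 (median 1.16, adjusted p = 2.32e-07), Kcnj13 by 1.94, Kcne2 by 1.60, Clic6 by 0.91 and Enpp2 by 0.65, and cell cycle genes lower in 14 of 30 (adjusted p = 9.04e-15), among them Aurkb (-0.43), Ccnb1 (-0.39), Ccna2 (-0.30) and Mki67 (-0.26). Synaptic genes were higher in 11 of 33 (adjusted p = 5.6e-08), such as Grin1 (0.96), Nlgn1 (0.50), Nrxn2 (0.43) and Gabrb3 (0.39), and dopaminergic and noradrenergic neuron genes in 3 of 7 (adjusted p = 0.00329), Ret (0.78), the dopamine synthesis gene Th (0.67) and Nr4a2 (0.44), with Foxa2 at 0.97 (adjusted p = 0.0535). Under an estimated correlation, adjusted p = 0.0759 for the first 2 lists, adjusted p = 0.197 for synapses and adjusted p = 0.1 for the last. With adjustment within each list, 9, 23, 23 and 6 members passed. Y-linked genes were higher in Sert KO as a list (median 4.22, adjusted p = 0.0163; 0 of 4 called by limma, 4 at an unadjusted p under 0.05, 4 adjusted over the list alone) and X-linked genes that escape inactivation lower, Kdm6a (-0.57) and Ddx3x (-0.17) among 4 (adjusted p = 0.0173; 3 adjusted over the list alone). These 2 lists had adjusted p = 0.39 and 0.268 with an estimated correlation, and neither passed without Oct3 KO library 1. The sex of the embryos is not given, and with the Y-linked level as a covariate the count was 1323. It was 1019 without Oct3 KO library 3 and 623 with 4 degrees of freedom fewer.

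Brains labelled Tph1 KO and Oct3 KO differed in 667 genes, 385 higher in Tph1 KO. Hddc3 (3.86), Gfer (4.38), Trip10 (3.85) and Olig3 (195 ± 113 against 43.4 ± 26) were higher in Tph1 KO and the X-linked Xlr3b (35.4 ± 17.6 against 153 ± 62.4) lower, besides copies with shared reads (Rps13-ps1 7.49, Rps13 -2.84, Rps13-ps2 -6.04, Rps2-ps10 -5.48, Hmga1-rs1 -7.73). With a pseudocount of 5 the difference was 3.23 for Hddc3, 3.60 for Gfer, 6.35 for Rps13-ps1 and -4.65 for Rps13-ps2. Glutamatergic neuron genes were lower in Tph1 KO in 4 of 14 and higher in 1, Lhx5 (0.62), with Neurod6 (-1.80), Neurod2 (-1.44) and Bcl11b (-0.72) lower (adjusted p = 4.09e-05), and passed with an estimated correlation (adjusted p = 0.00642). Definitive erythroid genes were higher in 6 of 14 (adjusted p = 2.54e-06), such as Gypa (1.59), Spta1 (1.37), Ermap (1.12) and Epor (1.10), and telencephalon genes lower in 4 of 14 (adjusted p = 4.09e-05), Neurod6, Foxg1 (-1.11), Tbr1 (-0.89) and Lhx2 (-0.47). Once the correlation was estimated, adjusted p = 0.264 and adjusted p = 0.254 for the latter 2. Over the list alone, 1 glutamatergic gene was higher and 7 lower, 10 erythroid genes were higher and 6 telencephalon genes lower. The count was 434, 378 and 418 without Oct3 KO libraries 1 and 2 and Tph1 KO library 2, and 238 with 4 degrees of freedom fewer.

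The 3 knockouts shared more calls than independent lists would, but they also share the 5 WT libraries. In all 101 genes were called in the same direction in at least 2 knockouts, 62 higher and 39 lower. Sert KO and Oct3 KO shared 56 rises and 28 falls, where independent lists would share 9.61 and 8.96, and 6 genes went opposite ways. Sert KO and Tph1 KO shared 11 and 12 (2.33 and 3.11 if independent; 7 opposite), and Tph1 KO and Oct3 KO 7 and 3 (0.259 and 0.523; 2 opposite). The log2 differences of each pair over all genes correlated by 0.314, 0.345 and 0.235 (Sert and Tph1, Sert and Oct3, Tph1 and Oct3), below the 0.519, 0.523 and 0.501 that 50 simulations of unchanged groups gave from the shared WT alone; genes are not independent replicates. The covariances were 0.0329, 0.0456 and 0.0268 against simulated values of 0.024, 0.0243 and 0.0241. With WT libraries 1 and 2 as the control of one knockout and 3 to 5 as that of the other, both ways round, the correlations were 0.038 and 0.051, 0.089 and 0.137, and -0.022 and 0.013. In these fits 4 and 9, 18 and 11, and 3 and 3 genes were called in the same direction. In opposite directions 0 and 5, 0 and 3, and 2 and 0 genes were called. The number in at least 2 knockouts was 45 without WT library 3, 67 without WT library 5, 50 and 59 without Oct3 KO libraries 2 and 1, 192 without Sert KO library 5 and 18 with 4 degrees of freedom fewer.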

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

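The tests of Slc6a4 and of the calls within 20 Mb of each targeted gene, against other chromosomes and against the rest of its own, were chosen after these results were seen, as were the covariates of Y-linked genes and adult globins.

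Among 126 groups of libraries checked for a single value far from the rest, 9 had one, where chance alone gives 6.3. In placenta, Prl3d1 was 1424 in E12.5 male library 3 (617 to 986 in the other 7), Hbb-y was 3148 in E9.5 female library 3 (750 to 1232 in the other 7) and Tph1 was 1 in E9.5 male library 2 (0 in the other 3). In brain, Tph1 was 9 in Oct3 KO library 4 (5 to 6 in the others), Tph2 was 18 in Sert KO library 5 (4 to 9) and 2 in Tph1 KO library 2 (6 to 7), Pop4 was 992 in Sert KO library 5 (705 to 777), Prkaa1 was 70 in Oct3 KO library 4 (6 to 22) and Hbb-bh1 was 3248 in WT library 3 (1841 to 2239).

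In 9 genes the difference between male and female placentas itself differed between the stages, by the F test of the interaction: Kng1 (F = 31.0), Dpy19l4 (25.3), Btk (20.4), Nudt12 (20.1), Pgam1-ps2 (20), Ice2 (19.9; differences of 0.56, -0.57 and 0.39 over the stages in order), Gal3st2 (18.7; 0.77, -0.84 and 1.81), Kif1b (18.6; 0.05, -0.24 and 0.35) and Ap1g2 (17.6; 0.03, -0.53 and 0.65). Their adjusted p ran from 0.00622 to 0.0468, each stage had 4 libraries per sex, and with 4 degrees of freedom fewer limma called 0 genes (1127 at an unadjusted p under 0.05).

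Other splits of the same libraries into groups of the same sizes were tried, with 100 splits drawn where there were more. The real split gave the most calls, 1 of 100 splits, for each stage comparison: 9299 against 6860 in the highest other split for E12.5 and E9.5, 10117 against 7882 for E17.5 and E12.5, and 11629 against 9931 for E17.5 and E9.5. It did so too (1 of 100) for Sert KO (1985 against 1857), Tph1 KO (81 against 6) and Oct3 KO (271 against 1) against WT, for Sert KO against Tph1 KO (2445 against 1805), Sert KO against Oct3 KO (1593 against 897) and Tph1 KO against Oct3 KO (667 against 1), for the interaction with the sexes shuffled within stages (9 against 1), and for sex at E12.5 (1 of 35 splits, 55 against 26). By this count alone chance can be excluded for these, but the authors' removal of unwanted variation had used the real groups, which favours the real split over the others. In 20 simulations with no difference between the groups, such a removal gave a median of 11.5 and at most 1308 calls for Sert KO against WT, and 4.5 and at most 792 for sex at E12.5, above the 55 seen there. The splits therefore do not settle whether the counts for sex, the interaction or the knockouts exceed what the removal can produce. For sex at E9.5 and at E17.5, 2 of 35 splits gave as many calls (11 against 16 in the highest other, and 36 against 66), so chance cannot be excluded there.

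In brains labelled Sert KO, cell cycle genes were lower and postmitotic neuron genes higher than in WT, with a gap of 0.55 between the medians of the 2 lists, although neither list passed with an estimated correlation (adjusted p = 0.0515 and 0.195). With the Y-linked level as a covariate 110% of the gap was left. The slope of that covariate rests on differences within groups, which the authors' removal had reduced, and Y-linked levels were spread unevenly over the labels. The covariate thus cannot decide on embryo sex. A source in 1 of the 2 runs of embryo numbers was argued against, since the run with the smaller gap kept 79.2% of it. With that run alone (embryos 788 to 790), 4 of the described list results for Sert KO against WT fell short of the threshold and 8 stayed the same. With embryos 716 to 718 alone, 1 fell short. Somewhat older embryos may account for it. Embryonic minus adult globins differed by -1.20 from WT (-0.96 ± 0.453, n = 6, against 0.24 ± 0.358, n = 5, exact permutation test, p = 0.00216, adjusted over 3 knockouts 0.00648). This ratio fell with age in the placentas (means of -1.50, -3.01 and -12.5 at the 3 stages). Placenta is another tissue, so its values give no amount of age for the brains. Oct3 KO brains also had a lower globin ratio (-0.72, exact permutation test, p = 0.0159, adjusted 0.0239), yet with limma 0 of 30 cell cycle and 0 of 23 neuronal genes were called in them (1 and 2 at an unadjusted p under 0.05), and Tph1 KO differed by 0.23 (p = 0.278, exact permutation test). With the adult globin level as a covariate 99% of the gap was left. That level is only 1 part of the ratio, and it overlapped between the groups (12.789 to 13.522 in WT, 13.037 to 13.965 in Sert KO). The covariate therefore cannot decide whether the embryos were older. An effect of the genotype stays open too, untested, as the label goes with the gap and the lower ratio. A difference in the region dissected was not tested (6 of 14 telencephalon genes were higher).

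Slc6a4 RNA was 3.38 higher on the log2 scale in brains labelled Sert KO than in WT. More serotonergic neurons in the dissected tissue were argued against, because the other 12 genes of the list had a median difference of 0.224 (SD 0.335, from -0.49 to 0.85) and the 7 of them above the filter 0.145 (SD 0.254), both far below 3.38; the other 5 were too low to test, among them Tph2 (5.6 in WT, 8.33 in Sert KO) and Fev (2.0 and 3.5). Reads from the altered allele or from DNA brought along with it could not be decided: of 23 tested genes within 1 Mb, 4 were called, with a median difference of -0.002. The tables give no values per exon, so an altered but transcribed allele may be a source and cannot be told apart from a change in the regulation of the gene. A wrong label was not tested.

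Called genes clustered near the targeted gene in Oct3 KO (odds ratio 7.21 within 20 Mb against other chromosomes, 9.61 against the rest of chromosome 17), which is consistent with DNA of another strain kept around the altered gene. In Tph1 KO the odds ratio was 8.96 against other chromosomes, so calls gathered on chromosome 7. It was 1.36 against the rest of that chromosome (interval 0.554 to 3.16), where 2.53% of genes were called against 0.393% on other chromosomes. The share was 4.35% from 40 to 80 Mb away and 0.508% beyond. A kept segment longer than 20 Mb would reach into that rest, so this comparison cannot decide on strain DNA in Tph1 KO. In Sert KO the odds ratio was 1.09, with 13.9% of genes elsewhere called too. Strain DNA around Slc6a4 therefore cannot be told apart from its absence. A WT group from another C57BL/6 substrain than the knockouts was weighed for Crb1, which was higher in all 3 (1.62, 1.77 and 1.45). Nnt, taken to be expressed less in C57BL/6J than in C57BL/6N, differed by 0.018, 0.004 and 0.362 from WT, with lower bounds of -0.42, -0.45 and -0.10. The rule set beforehand, a lower bound above a fixed limit in any of the knockouts, was met, which it counted against another substrain. That rule let 1 knockout decide for all 3, and Nnt is a single gene. It cannot show which DNA lay around Crb1, so a substrain difference stays undecided. A fall of Nnt smaller than these bounds is not excluded in Sert KO and Tph1 KO. An effect of losing either gene on its neighbours was not tested.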

How the results depend on the processing

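The serotonin list without Slc6a4, the counts without the targeted chromosomes and the fit without E9.5 female libraries 1 and 3 were also chosen after the data were seen. The 3 stage counts moved by over 1.5 times only with a minimum absolute log2 difference of 1 (2199, 2261 and 4217). That minimum gave 7, 15 and 13 for sex at the stages in order, 125, 18 and 71 for Sert, Tph1 and Oct3 KO against WT, and 183, 174 and 165 for Sert against Tph1, Sert against Oct3 and Tph1 against Oct3. With 4 residual degrees of freedom fewer, as many as the factors removed, sex gave 2, 9 and 8, the knockouts 897, 19 and 86, the pairs of knockouts 1198, 623 and 238, the overlap 18 and the interaction 0 (1127 genes at an unadjusted p under 0.05 in limma). Fits of the groups compared alone have fewer samples and gave 3, 8 and 6 for sex, 1154 for Sert KO, 32 for Tph1 KO and 1459 for Sert against Tph1 KO. Sex at E9.5 also moved to 6 with a pseudocount of 5, 34 without the filter, 6 with quantile normalization, 7 without the trend and 2 without female libraries 1 and 3. The pairs of neighbouring embryo numbers as a fixed block gave 4, 15 and 14 for sex; the deviations of only 2 of 12 pairs correlated above 0.1 (-0.799 to 0.639), so the values do not establish that these embryos are paired. The interaction gave 43 without the filter and 4 without the trend. Single runs of embryo numbers gave 3263 (716 to 718) and 385 (788 to 790) for Sert KO, so the runs differed and the first gave more calls than all 6 libraries, 27 (682 to 684) for Tph1 KO, and 74 (697 and 700) and 78 (748 to 750) for Oct3 KO; the cause was not tested. Without chromosome 7, which removes tested genes, Tph1 KO gave 53. Of the list tests, 9 in place of 134 passed with an estimated correlation. Other causes were not tested.

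With each library left out, the counts ranged from 3 to 99, 20 to 72 and 15 to 151 for sex at the 3 stages, 2 to 27 for the interaction, 1187 to 2814, 40 to 136 and 144 to 378 for Sert, Tph1 and Oct3 KO, 1743 to 2614, 1019 to 1941 and 378 to 812 for the pairs of knockouts, and 45 to 192 for the overlap. Those beyond 1.5 times for the brains were, for Sert KO, WT library 3 (1187); for Tph1 KO, WT 3 (40), Tph1 KO 2 (48) and 5 (52) and Sert KO 5 (136); for Oct3 KO, Oct3 KO 1 (164) and 2 (144) and WT 5 (179) and 3 (75 higher and 87 lower); for Sert against Oct3, Oct3 KO 3 (1019); for Tph1 against Oct3, Oct3 KO 1 (434) and 2 (378) and Tph1 KO 2 (418); and for the overlap, WT 3 (45) and 5 (67), Oct3 KO 1 (59) and 2 (50) and Sert KO 5 (192). For sex at E12.5 they were female 1 (36), 2 (30), 3 (33) and 4 (25) and male 1 (29) and 4 (20), and at E17.5 female 1 (19) and 2 (15) and male 1 (151) and 3 (22). Sex at E9.5 moved to 99, 3 and 4 without female 2, 3 and 4 of that stage, to 74, 3, 3 and 4 without its males 1 to 4, to 3 and 6 without E12.5 female 2 and 4, to 17 without E12.5 male 4, to 3, 3 and 7 without E17.5 female 1, 2 and 4, and to 7 and 6 without E17.5 male 1 and 3. The interaction gave 2 without E12.5 female 1, male 1 or male 4 or E17.5 female 1 or 2, 3 without E9.5 female 4 or male 1, 3 or 4, and 14, 18, 23 and 27 without E12.5 female 2, female 3, male 3 and E9.5 female 2.

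The named genes gave 523 results. None reversed under any alternative, 100 fell short of the threshold under at least 1 (545 times in all) and 26 passed it where they had not (56 times). A pseudocount of 5 changed the fold by over 1.5 times in 28 of 264 results of named genes in placenta and 16 of 254 in brain, by 4.86 times at most (Eif2s3y for sex at E17.5). Of 86 list results, 76 fell short under at least 1 (172 times) and 2 passed where they had not. The Y-linked list between Sert and Oct3 KO reversed with the Y-linked level as a covariate (median 0.044, adjusted p = 0.98), which removes that level by construction. The serotonin and monoamine list of Sert KO without Slc6a4 had a median of 0.24 (adjusted p = 0.00565, and 0.0515 with an estimated correlation). Differences of genes that were not called changed sign in 34 of 4188 comparisons. The median difference of all genes stayed within 0.05 of 0 as deposited, with median-of-ratios rescaling and with quantile normalization, in each of the 12 contrasts, yet the share of calls that were higher moved: from 57.3% to 52.8% and 51.4% for Sert against Tph1 KO, 57.7% to 53.0% and 51.0% for Tph1 against Oct3 KO and 56.0% to 53.2% and 51.2% for Sert KO against WT. The list tests were not run with fewer degrees of freedom or with correlated runs (correlations of 0.022 and 0.011 in placenta and brain). Read depth is unknown, so genes at a few units, such as Tph1 and Tph2 in brain, cannot be called present or absent.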

Other observations

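Counting the genes called in all 3 knockouts was planned, and naming the 8 genes so counted was decided after their values were seen.

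Of the genes called in the same direction in all 3 knockouts, 6 were higher and 2 lower than in WT. Crb1, a cell polarity gene of retina and brain, was 46.0 ± 12.1 in WT (n = 5), 140 ± 15.9 in Sert KO (n = 6), 158 ± 30.8 in Tph1 KO (n = 5) and 125 ± 18.2 in Oct3 KO (n = 5). Gm14325 (0.92, 1.13 and 1.03 in Sert, Tph1 and Oct3 KO), Gm14326 (0.85, 1.15 and 1.01) and Gm14410 (0.64, 0.88 and 0.71) lie on chromosome 2 between 177183453 and 177957297 and were higher, as were Etohi1 (0.73, 0.88 and 0.79) and Adss (0.22, 0.34 and 0.29), an enzyme gene of purine synthesis. Gm5619 (-0.52, -0.45 and -0.50) and Hmgb1-ps3 (-0.45, -0.60 and -0.32) were lower. Because all 3 comparisons use the same 5 WT libraries, such a gene can also reflect those libraries.

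Y-linked RNA varied between the brains within each group and, as a list, was higher in Sert KO than in Oct3 KO (median 4.22, adjusted p = 0.0163 in limma's camera, and 0.39 with an estimated correlation); the labels give no sex. Eif2s3y ranged from 3 to 2797 in WT, from 14 to 11535 in Sert KO, from 2 to 3862 in Tph1 KO and from 0 to 1597 in Oct3 KO, and Kdm5d from 125 to 2646, 171 to 3764, 87 to 2932 and 14 to 1566. The X-linked Mid1 was 1704 ± 483 in Sert KO and 2340 ± 254 in Tph1 KO, against 942 ± 126 in WT and 938 ± 52.0 in Oct3 KO.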
